A study of Arabidopsis thaliana with 8 samples.

How the data were processed

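Total RNA from 4 root zones of Arabidopsis Columbia seedlings, 2 samples per zone, was extracted with a column kit and turned into biotinylated cRNA with a two-cycle amplification for Affymetrix arrays, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 signal per probe set and array, computed with MAS5, per the submitters' processing notes, and the version and chip definition are not given in the sources used here. All values were above 0. Trimmed by 2% at each end, the mean signal was 250.0 on each of the 8 arrays, so the deposited signals had been scaled to a common level. The design holds no sulfur-sufficient sample, and zone is its only factor.

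The deposited table holds 22810 probe sets. The 64 control probe sets were left out of the tests, and of the other 22746 the platform annotation paired 13513 with 1 gene, 503 with several and left 8730 unnamed here. Of the 13513, 13436 matched a locus tag in the gene table of assembly TAIR10.1, from which current names were taken and no coordinates were used. A probe set with several genes or none entered the tests and counts but was never named. Of the 271 loci in the gene lists fixed in advance, 30 had a named probe set.

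Signals were turned to log2 without an offset, and probe sets in the lowest 40% of mean signal over all arrays (42.5 or less) were left out, which left 13647. The package limma 3.58.1 in R 4.3.3 fitted 1 mean per zone to all 8 arrays, with 4 residual degrees of freedom and a prior variance that follows the mean signal (eBayes with trend, 6.5 prior degrees of freedom). Contrasts were zone 2 against zone 1, zone 3 against zone 2, zone 4 against zone 3 and zone 4 against zone 1, and a moderated F-test covered all zones. Benjamini-Hochberg adjustment was made over the 13647 probe sets of each test. A probe set counted as changed at an adjusted p under 0.05 and at least 2-fold, and in the F-test at the adjusted p alone. These choices, the comparisons, 17 gene lists and the rule for naming genes were fixed before the data were examined. The tests of contrasts and lists are two-sided. Errors beside signals are SDs of 2 arrays, and errors beside log2 differences are moderated SEs.

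The rule named, for each contrast, the 10 genes with the largest log2 difference in each direction among changed probe sets with 1 gene, whose 2 arrays of one zone both lay above the 2 of the other and whose higher zone mean reached the median of all probe-set means, 75. It added up to 4 members of each gene list with the largest differences, passing or not, and allowed the SULTR, APR, LSU and SDI genes. The expression of gene groups was tested with limma's camera, at a preset correlation between genes of 0.01, for each list with at least 3 tested members. A locus with several probe sets was represented by the one with the highest mean. Because 6 of the 17 fixed lists had no named member, 19 lists were added from the named genes. They were drawn up after the annotation had been seen and before their members were tested, when the signals of a few probe sets, ATPS3 among them, had already been looked at. Adjustment covered all 92 tests, 23 lists in 4 contrasts, of which 31 passed. All but 4 of the lists tested were added ones, and the fixed lists are called fixed in the results. With an estimated correlation 0 of the 92 passed.

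The fit was tested on simulated arrays with the spread of the real ones and 200 probe sets changed in zone 4. In zone 4 against zone 1, over 13647 probe sets, it recovered 12%, 32%, 64% and 78% of 50 probe sets each at log2 changes of 1.5, 2, 3 and 4, and called 6 unchanged ones. The simulated noise was independent between probe sets, so these numbers do not cover deviations that many genes of an array share. The simulation changed 200 probe sets where the real comparison called 1957, so recovery there may differ. Alternatives were quantile normalization, centring each array on its median, no filter, a filter at 60%, an offset of 32, a floor at the 40th percentile of each array, a prior variance without trend or with robust estimation, a replicate block, no minimum fold, fry in place of camera, and leaving out each array. Leaving out 2 arrays together and testing the fixed lists alone were added later. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.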

Results

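Sections of Arabidopsis thaliana roots (ecotype Columbia) were profiled on Affymetrix expression arrays in 4 longitudinal zones, which the labels number 1 to 4 and describe as developmental stages. Seedlings spent 5 days on Murashige and Skoog (MS) medium and then 3 hours on a sulfur-deficient medium before dissection, and all 8 samples, 2 per zone, had this treatment. The comparisons therefore ask how transcript levels differ along a root held at low sulfur, and none of them measures the effect of low sulfur itself. The labels do not say which zone lies at the root tip. They also do not say that the 2 samples of a zone came from separate plants or cultures, so the p-values measure the spread between these samples, which may be technical. Median signals of the arrays ranged from 57.8 to 79.7, and the number of arrays limits the precision of every value.

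Zone 1 and zone 3 were the least alike of the zones. Over the 13647 probe sets tested, the log2 signals of zone 1 and zone 3 arrays correlated with a mean r of 0.613, against 0.732 for zones 1 and 4, 0.802 for zones 1 and 2, and 0.862 for zones 3 and 4. The 2 arrays of a zone correlated with r = 0.896, 0.924, 0.899 and 0.938 in zones 1 to 4. These correlations are across probe sets, which are not independent replicates. The arrays of zones 2 and 3 were spread along the same axis. Zone 2 replicate 1 correlated with the zone 1 arrays at 0.848 and 0.85, and zone 2 replicate 2 at 0.754 and 0.754. Zone 3 replicate 2 correlated more closely with zone 2 replicate 2 (r = 0.916) than with the other zone 3 array. The 3'/5' signal ratio of the GAPDH control transcript ranged from 13.2 to 64.3 across arrays, both extremes lying in zone 1.

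**Figure D1:**
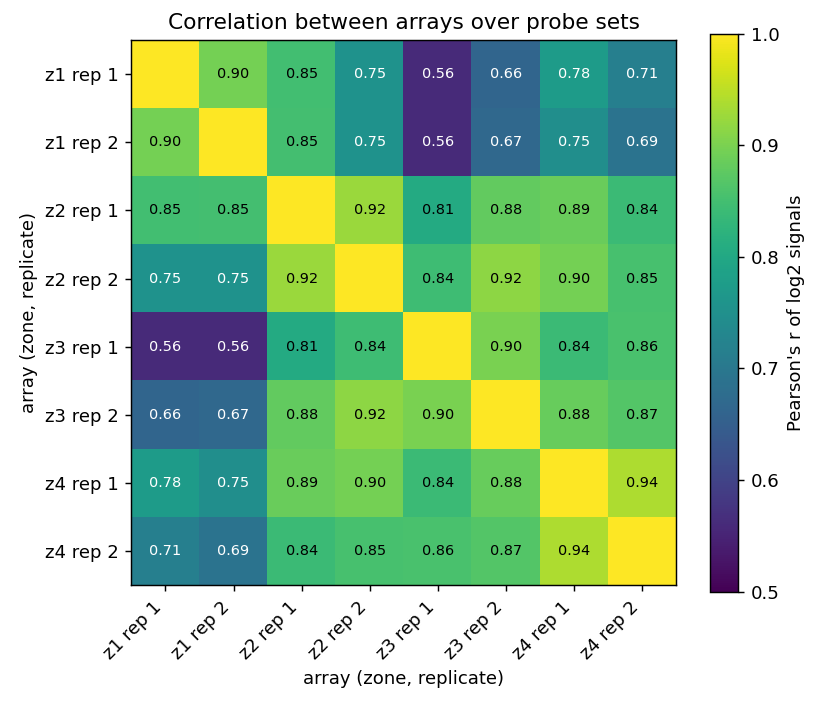
Pearson's r of log2 signals between each pair of the 8 arrays, over 13647 probe sets, with zone (z) and replicate (rep) on both axes. The pairs of zone 1 and zone 3 arrays have the lowest values, 0.559 to 0.668.

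Genes with their highest signal in zone 1 formed the largest class of those that differed between zones, and genes highest in zone 2 the smallest. BBM (AT5G17430), an AP2-type transcription factor gene of the root meristem, had mean signals of 375 ± 320, 8.18 ± 0.81, 6.21 ± 6.5 and 195 ± 55 in zones 1 to 4 (SD, n = 2 each). The Aurora kinase gene AUR2 had 982 ± 570, 270 ± 62, 89.2 ± 21 and 701 ± 190. XTH21, which encodes a xyloglucan endotransglucosylase of the cell wall, went the other way, with 13.4 ± 10, 157 ± 130, 530 ± 21 and 820 ± 31. By limma's moderated F-test, 3673 of 13647 probe sets differed between zones. Of these, 1705 (46.4%) had their highest mean in zone 1, 168 (4.6%) in zone 2, 1206 (32.8%) in zone 3 and 594 (16.2%) in zone 4. The number passing was 2196 without zone 3 replicate 1 and 2340 without zone 4 replicate 2.

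**Figure D2:**
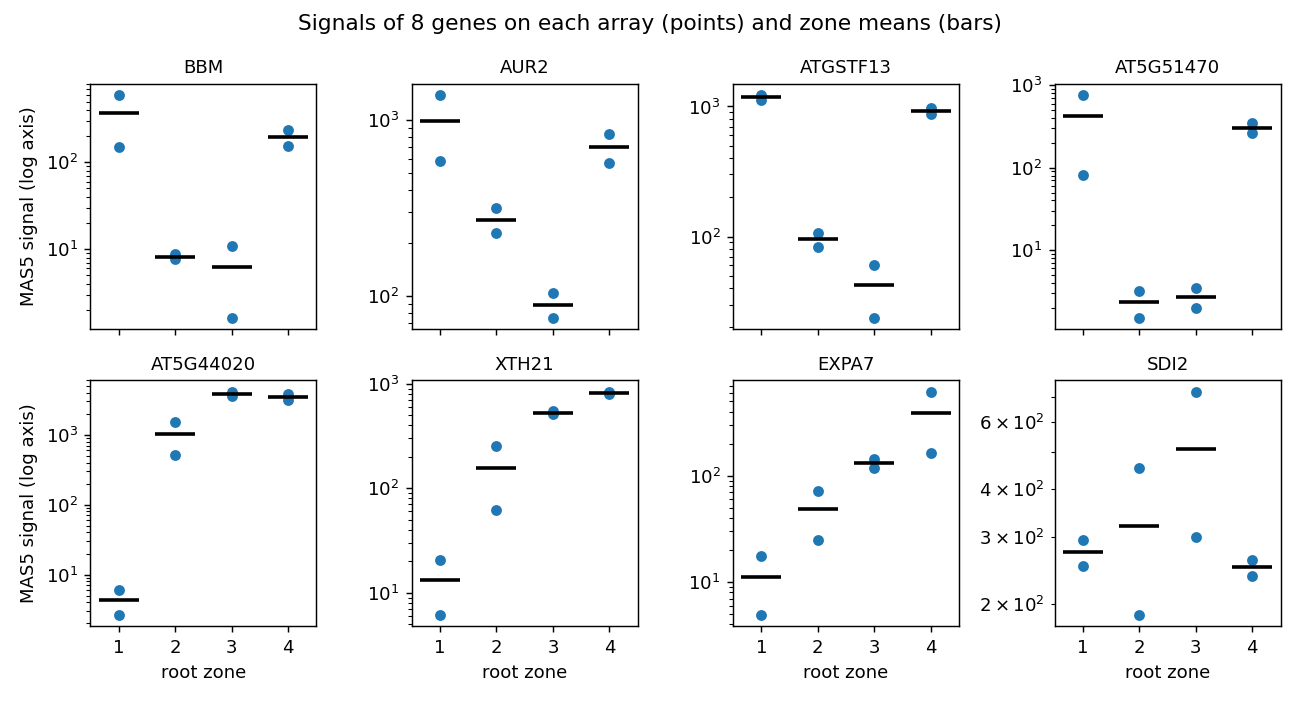
MAS5 signal (log axis) of 8 genes against root zone, with a point for each of the 2 arrays per zone and a bar for their mean. BBM is high in zones 1 and 4 (means 375 and 195) and low in zones 2 and 3 (8.18 and 6.21), and EXPA7 has means of 11.2, 48.4, 131 and 391 in zones 1 to 4.

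Peroxidase and acid phosphatase genes were among those most strongly higher in zone 2 than in zone 1, and a meristem regulator and GH3 family genes among those most strongly lower. AT5G44020, of the acid phosphatase family, was higher in zone 2 (1030 ± 720 against 4.35 ± 2.4, SD, n = 2; log2 difference 7.81, SE 0.52, adjusted p = 0.00014). Its relative AT1G04040 was 75.8-fold higher (2840 ± 1700 against 34.3 ± 5.5, adjusted p = 0.00025). The class III peroxidase genes AT4G30170 and AT2G37130 were higher by 5.74 and 5.88 on the log2 scale (SE 0.53 and 0.77). AT3G05920, AT5G44820, AT1G07795, AT2G20670, AT5G06930 and the receptor-like kinase gene AT1G51850 completed the 10 named genes that were higher, with log2 differences from 5.71 to 6.79. BBM was lower in zone 2 by a log2 difference of -5.19 (adjusted p = 0.013). AT5G51470 and AT1G23160, of the GH3 family of acyl acid amido synthetases, had log2 differences of -6.85 (SE 1.22) and -5.51 (SE 1.31). The glutathione transferase gene ATGSTF13 was 12.4-fold lower (95 ± 16 against 1170 ± 80, adjusted p = 0.0018). The polygalacturonase genes AT3G15720 and AT1G65570 were 16.0-fold and 11-fold lower. The other named genes that were lower were hemb2, AT3G42860, AT1G48580 and AT3G15680, with log2 differences from -4.75 to -3.45. Several of these differences rest on signals near the dim end of the arrays: with signals under the 40th percentile of their array raised to it, the log2 difference was 4.89 for AT5G44020, 4.21 for AT2G37130, -2.91 for BBM, -2.65 for AT5G51470 and -2.96 for AT1G23160, and AT1G51850 was no longer called (1.58, adjusted p = 0.13). In that setting AT3G05920, AT5G44820, AT1G07795, AT2G20670 and AT5G06930 had 1.68 to 3.7, and hemb2, AT3G42860 and AT1G48580 -2.59 to -1.82, and all were called.

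Cell division and ribosome production genes were lower in zone 2 as groups by camera at the preset correlation. With fry in place of camera neither the division nor the rRNA list passed (adjusted p = 0.05 and 0.086). Of 17 cell division and chromosome segregation genes tested, 7 were lower and none was higher, with a median log2 difference of -1.44 (camera, adjusted p = 4.7e-05; adjusted p = 0.44 with an estimated correlation). KINESIN-12B, a phragmoplast motor, was 5.83-fold lower (49.2 ± 20 against 292 ± 140, SD, n = 2, adjusted p = 0.025). AUR2 and 3xHMG-box1 were 3.36-fold and 4.15-fold lower. Of 8 genes for rRNA synthesis and processing, 4 were lower (list median -1.32, adjusted p = 0.0017; adjusted p = 0.5 with an estimated correlation). Among them were the nucleolar gene YAO and the RNA polymerase I subunit genes NRPA1 and NRPA2, with log2 differences of -2.06, -1.84 and -1.82. Of the 21 genes in the fixed list of mitosis genes, 3 had a named probe set, AUR1, AUR2 and AUR3. These 3 are also in the division list, so the 2 lists are not independent in any comparison. The fixed mitosis list did not pass (median -0.95, adjusted p = 0.12), with 1 gene lower over all genes tested and 1 adjusted over the list alone. Of 5 cytosolic ribosomal protein genes, 0 changed over all genes tested in limma and 1 was lower adjusted over the list alone (median -0.21, list adjusted p = 0.35). The 39 plastid-encoded genes tested had a median of -0.33 (adjusted p = 0.036; adjusted p = 0.63 with an estimated correlation) and did not pass without zone 1 replicate 1 (0.89), zone 2 replicate 1 (0.58) or zone 3 replicate 1 (0.062). Their 1 lower member, psbK, had a log2 difference of -1.73 (adjusted p = 0.021) and lost the call without zone 1 replicate 1 (0.077), zone 2 replicate 1 (0.077) or zone 2 replicate 2 (0.15).

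The lists of autophagy, sugar transporter and citric acid cycle genes were higher in zone 2 as groups by camera at the preset correlation, with a minority of members called in each. Of these, fry called the citric acid cycle list (adjusted p = 0.034) but not the autophagy or sugar transporter list (adjusted p = 0.089 and 0.05). The autophagy list held 8 ATG8 genes, whose proteins coat autophagosomes, and the conjugating enzyme gene ATG3. Of these 9, 3 were higher (list median 1.03, adjusted p = 0.013; adjusted p = 0.5 with an estimated correlation). They were ATG8E at 5.75-fold, ATG8F at 2.92-fold and ATG8H at 2.51-fold, and ATG8E was not called with dim signals raised to the 40th percentile of their array (log2 difference 0.52, adjusted p = 0.54). Of 6 SWEET and tonoplast sugar transporter genes, 2 were higher (list median 0.88, adjusted p = 0.025; adjusted p = 0.44 with an estimated correlation). SWEET16 had 179 ± 4.5 against 29.1 ± 7.4 and TMT1 1140 ± 350 against 269 ± 7.2 (SD, n = 2). The citric acid cycle and pyruvate dehydrogenase list of 10 genes had a median of 0.76 (adjusted p = 0.016; adjusted p = 0.44 with an estimated correlation). Its 1 higher member, the succinate dehydrogenase gene SDH2-1 at 2.13-fold, lost the call when any array but zone 1 replicate 2 was left out (adjusted p from 0.055 to 0.25). The autophagy and sugar transporter lists did not pass without zone 1 replicate 2 (adjusted p = 0.069 and 0.082), nor the citric acid cycle list without zone 1 replicate 1 (0.1).

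In total 1645 probe sets changed between zones 1 and 2 by limma, 993 of them higher (60.4%) and 652 lower in zone 2. That split was not stable: with each array centred on its median, which put the median log2 difference of all probe sets tested at -0.11, 808 were higher (52.2%) and 740 lower. With zone 2 replicate 1 and zone 3 replicate 2 left out together, a setting chosen after seeing the data, 600 were higher and 636 lower. Of the 46 called genes followed singly, those of the rule and of the lists, 13 kept the call without zone 2 replicate 2, 29 without zone 1 replicate 1, 37 without zone 1 replicate 2, 35 without zone 2 replicate 1, 35 without zone 4 replicate 1, 34 without zone 4 replicate 2 and 45 without either zone 3 array. The count itself was 70 without zone 2 replicate 2, the zone 2 array less like zone 1, 920 without zone 4 replicate 1, 921 without zone 4 replicate 2, and 804 with a prior variance that did not follow the signal.

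Between zones 2 and 3 no single gene passed, while the same division and ribosome production groups were lower again in zone 3 by camera at the preset correlation. With fry in place of camera neither group passed (adjusted p = 0.069 and 0.082). The division list had a median log2 difference of -1.29 (camera, adjusted p = 7e-05; adjusted p = 0.44 with an estimated correlation), and the rRNA list -1.26 (adjusted p = 0.00011; adjusted p = 0.44 with an estimated correlation). The histone kinase gene Haspin had signals of 5.52 ± 1.4 in zone 3 and 65.2 ± 12 in zone 2 (SD, n = 2; log2 difference -3.58, SE 0.59, adjusted p = 0.1). BUBR1, of the spindle checkpoint, had 5.74 ± 3.6 and 56.8 ± 19 (adjusted p = 0.1). In the fixed mitosis list AUR1, AUR2 and AUR3 had log2 differences of -1.59, -1.6 and -2.29. The zone 3 signals of several of these genes were near the dim end of the arrays: with signals under the 40th percentile of their array raised to it, the log2 difference was -0.64 for Haspin (adjusted p = 0.46), -0.44 for BUBR1 (adjusted p = 0.68) and -0.98 for AUR3 (adjusted p = 0.29), while AUR1 and AUR2 had -1.59 and -1.6. With the signals as deposited, all 3 AUR genes were lower adjusted over the list alone, against 0 over all genes tested in limma (list adjusted p = 0.013; adjusted p = 0.46 with an estimated correlation; 0.078 without zone 3 replicate 1). The list of DNA polymerase, replication licensing and histone genes, with 12 members, had a median of -0.70 (adjusted p = 0.0054, and adjusted p = 0.53 with an estimated correlation). The expansin and xyloglucan endotransglucosylase list of 18 genes was higher in zone 3, with a median of 0.78 (adjusted p = 0.011; adjusted p = 0.44 with an estimated correlation; 0.11 without zone 3 replicate 1). Its member XTH18 had signals of 1140 ± 210 in zone 3 and 240 ± 17 in zone 2 (adjusted p = 0.1).

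Over all genes limma called 0 probe sets between zones 2 and 3, with 2470 at an unadjusted p under 0.05 where chance gives 682. The smallest adjusted p was 0.101. Without zone 3 replicate 2, the array that lay nearer to zone 2, 358 probe sets passed, 59 higher and 299 lower in zone 3. Without zone 3 replicate 1 there were 3, all lower and none named here.

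Several genes that were high in zone 1 and low in zones 2 and 3 had high signals again in zone 4. AT5G51470 was higher in zone 4 than in zone 3 (307 ± 61 against 2.73 ± 1, SD, n = 2; log2 difference 6.85, adjusted p = 0.031). BBM was also higher (195 ± 55 against 6.21 ± 6.5; log2 difference 5.53, adjusted p = 0.033) and ATGSTF13 was 24.4-fold higher (923 ± 60 against 42.1 ± 26; log2 difference 4.61, SE 0.43, adjusted p = 0.0075). The polygalacturonase gene AT1G65570 was 22.7-fold higher (adjusted p = 0.025) and IAA33, of the Aux/IAA family of auxin response repressors, was higher by 4.96 on the log2 scale (adjusted p = 0.046). AT4G26880, AT1G56680, AT3G59490, AT4G27400 and AT4G02800 were also higher, by 4.53 to 5.65 on the log2 scale. Some of the zone 3 signals were too dim for a firm difference. With signals under the 40th percentile of their array raised to it, AT5G51470 (log2 difference 2.87, adjusted p = 0.06), BBM (2.21, adjusted p = 0.054), AT4G26880 (2.07, adjusted p = 0.15), AT3G59490 (0.91, adjusted p = 0.28) and IAA33 (0.86, adjusted p = 0.29) were not called, while ATGSTF13, AT1G65570, AT1G56680, AT4G27400 and AT4G02800 were called, with 4.3, 3.91, 4.09, 3.92 and 2.87. Among the genes lower in zone 4, AT1G76640 had 27.8 ± 26 in zone 4 and 317 ± 180 in zone 3 (log2 difference -3.79, adjusted p = 0.028, or -2.68 with dim signals raised in the same way), and the transcription factor gene BZIP61 was 5.25-fold lower. AT1G76470, AT4G14980, AT5G62330, AT1G57590, AT2G02630, AT5G14150, AT3G62280 and AT5G16450 had log2 differences from -2.75 to -1.94.

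The lists of division and rRNA synthesis genes were higher in zone 4 than in zone 3 as groups by camera at the preset correlation. With fry in place of camera the division list passed (adjusted p = 0.042) and the rRNA list did not (adjusted p = 0.059). Of the 17 division genes 7 were higher and none lower, with a median log2 difference of 1.88 (camera, adjusted p = 9.7e-07; adjusted p = 0.44 with an estimated correlation). AUR2 was 7.82-fold and 3xHMG-box1 6.48-fold higher (adjusted p = 0.017 for both). Haspin had 103 ± 14 against 5.52 ± 1.4 (SD, n = 2, adjusted p = 0.015) and was not called with dim signals raised to the 40th percentile of their array (log2 difference 1.3, adjusted p = 0.12). In that setting 3xHMG-box1 was called with a log2 difference of 2.08, and AUR3, which sets the median of the mitosis list, had 1.27 in place of 2.58. In the fixed mitosis list 1 gene was higher over all genes tested and 3 adjusted over the list alone (median 2.58, list adjusted p = 0.0038; adjusted p = 0.44 with an estimated correlation). The rRNA list had a median of 1.57 with 1 of 8 members higher, IMP4 at 3.48-fold (list adjusted p = 5e-05; adjusted p = 0.44 with an estimated correlation). The citric acid cycle list was lower, with a median of -0.47 and 0 of 10 members past the limma threshold (list adjusted p = 0.0037; adjusted p = 0.44 with an estimated correlation). The shoot tissue check, 9 nuclear photosynthesis genes, had a median of 0.70 in the same comparison (adjusted p = 0.22). The 39 plastid-encoded genes tested did not pass (adjusted p = 0.82), with a median of 0.10 and a mean of 0.22 where the camera test pointed down, and with no member past the limma threshold.

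In total 288 probe sets changed between zones 3 and 4 by limma, 252 higher (87.5%) and 36 lower in zone 4. Of the 252, 217 had their highest mean in zone 1. With each array centred on its median, which moved the median log2 difference of all probe sets tested from 0.10 to -0.14, 93 changed, 66 higher (71%) and 27 lower. With a prior variance that did not follow the signal, 37 changed, and with a replicate block 127. Without either zone 4 array limma called 0, with 1468 and 1634 at an unadjusted p under 0.05, and 0 of the 24 called genes followed singly kept the call. Of these, 3 kept it without zone 3 replicate 1, 22 without zone 3 replicate 2, 12 and 15 without zone 2 replicates 1 and 2, and 21 and 20 without zone 1 replicates 1 and 2. The count was 26 without zone 3 replicate 1, 628 without zone 3 replicate 2, 97 without zone 2 replicate 1, 141 without zone 2 replicate 2, and 546 without zone 2 replicate 1 and zone 3 replicate 2 together, a setting chosen after seeing the data.

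**Figure D3:**
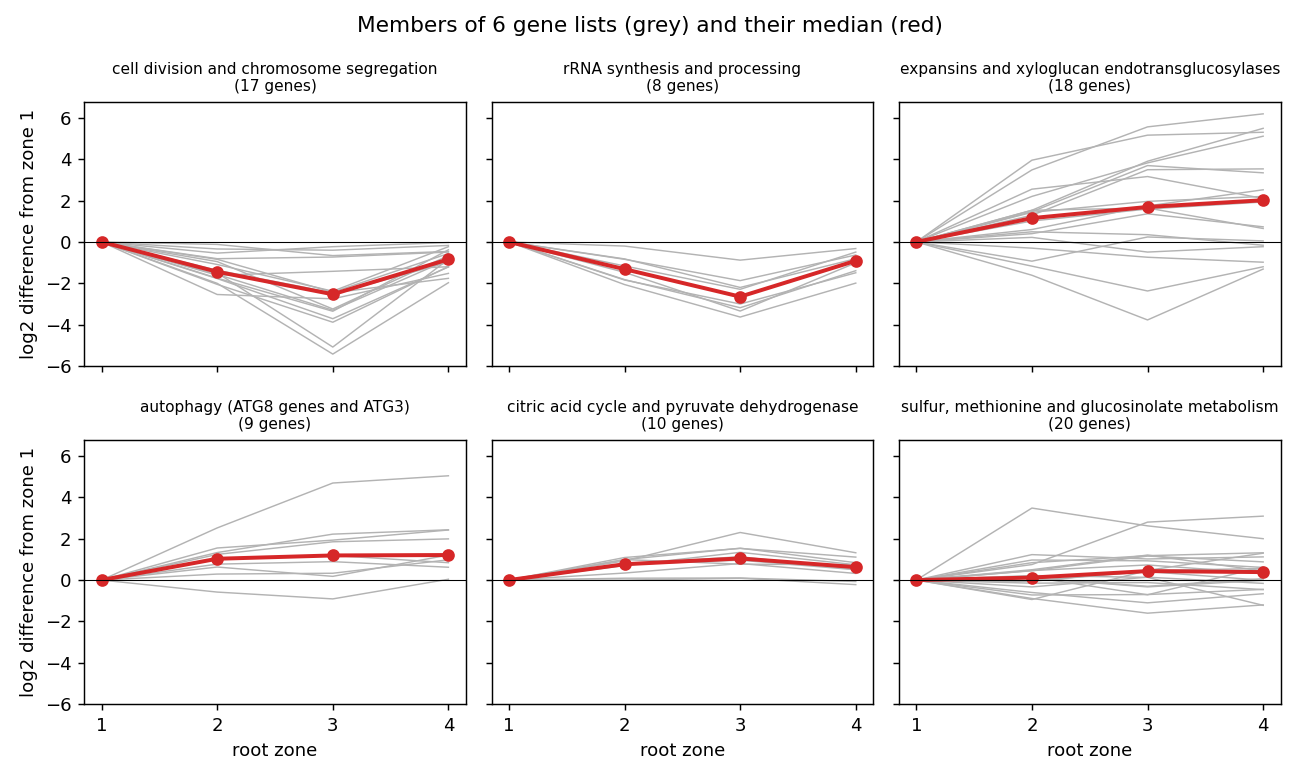
Log2 difference from zone 1 against root zone for the tested members of 6 gene lists (grey lines) and their median (red). The median of the division list is lowest in zone 3 and lies at -0.84 in zone 4, while the expansin and xyloglucan endotransglucosylase list reaches 2.02 in zone 4.

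Between zones 4 and 1, an acid phosphatase gene, a pair of peroxidase genes and a receptor-like kinase gene were among the 10 named genes most strongly higher in zone 4. AT5G44020 was 870-fold higher in zone 4 (3490 ± 450 against 4.35 ± 2.4, SD, n = 2; log2 difference 9.77, SE 0.52, adjusted p = 1.5e-05). The peroxidase genes AT5G17820 and AT5G66390 were 689-fold and 397-fold higher (adjusted p = 0.00038 and 0.014). The receptor-like kinase gene AT1G51850 was 403-fold higher (adjusted p = 0.00044). AT3G53980, TBL38, AT4G13580, AT3G28550, AT2G44300 and AT3G59370 had log2 differences from 7.80 to 8.77. Since zone 1 signals of these genes lay between 1.24 and 5.79, far under the 42.5 at which probe sets were filtered by their mean, the fold values are imprecise. With signals under the 40th percentile of their array raised to it, all 10 were called, with log2 differences from 2.93 for AT3G59370 to 6.85 for AT5G44020. The order of genes changed in that setting. AT1G51850 (4.2) and AT5G66390 (4.15) then lay below XTH21 (4.76) and the defensin-like gene LCR68 (6.09), which are not among the 10. The chaperone gene Hsp70-2 was 8.89-fold lower in zone 4 (132 ± 27 against 1160 ± 110, adjusted p = 0.00052) and AT3G10530 6.69-fold lower (adjusted p = 0.00087). The DEAD-box RNA helicase genes AT5G54910 and AT5G60990 were 6.79-fold and 4.93-fold lower. AT4G26600, AT3G15680, AT2G22100, AT2G34357, AT1G79150 and AT5G66540 were lower by 4.94-fold to 7.26-fold.

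The root hair, expansin and xyloglucan endotransglucosylase, and autophagy lists were higher in zone 4 than in zone 1 as groups by camera at the preset correlation. The root hair list fixed in advance had 3 members tested, and all 3 were higher both over all genes tested and adjusted over the list alone (camera, adjusted p = 0.0095; adjusted p = 0.44 with an estimated correlation). They were the expansin genes EXPA7 (391 ± 320 against 11.2 ± 8.9, SD, n = 2, adjusted p = 0.0032) and EXPA18 (711 ± 790 against 15.2 ± 16, adjusted p = 0.0081), and SCN1, a regulator of hair initiation, at 2.05-fold. Of 18 expansin and xyloglucan endotransglucosylase genes 9 were higher (list median 2.02, adjusted p = 0.0037; adjusted p = 0.44 with an estimated correlation), among them XTH21 at 73.0-fold and EXPA8 at 39.5-fold. EXPA7 and EXPA18 belong to this list as well, so it is not independent of the root hair list. Another cell wall list, 6 lignin and xylan genes, did not pass by camera (median 0.55, adjusted p = 0.23, 1 member higher). Of the 8 ATG8 genes and ATG3 in the autophagy list, 5 were higher, all of them ATG8 genes (list median 1.21, adjusted p = 0.00068; adjusted p = 0.44 with an estimated correlation). ATG8E was 33.0-fold, ATG8H 5.4-fold, ATG8F 5.35-fold and APG8A 3.98-fold higher. With dim signals raised to the 40th percentile of their array, XTH21, EXPA18, EXPA7, ATG8E and EXPA8 were called with log2 differences of 4.76, 3.87, 3.4, 3.03 and 1.68. Of the 9 nuclear photosynthesis genes in the shoot tissue check 3 were higher over all genes tested and 8 adjusted over the list alone (list median 2.18, adjusted p = 0.001; adjusted p = 0.48 with an estimated correlation). The 3 included the light-harvesting genes LHCB4.1 (283 ± 2.8 against 51.8 ± 31) and LHCB4.2 (95.7 ± 38 against 11.6 ± 1.7), the latter not called with dim signals raised in this way (log2 difference 1.6, adjusted p = 0.052). Whether shoot tissue in the zone 4 sections raised these genes over zone 1 was not tested. The 39 plastid-encoded genes tested were lower in zone 4, with a median of -0.42 (adjusted p = 0.013; adjusted p = 0.59 with an estimated correlation; 0.62 without zone 1 replicate 1 and 0.074 without zone 4 replicate 2). Of these 1 passed, psbK, which codes for a photosystem II subunit (132 against 446, log2 difference -1.76, adjusted p = 0.015), and not without zone 1 replicate 1 (0.058), zone 4 replicate 1 (0.11) or zone 4 replicate 2 (0.06). The rRNA list was lower, with a median of -0.91 and 1 member past the threshold, YAO at 3.98-fold (list adjusted p = 0.0079; adjusted p = 0.5 with an estimated correlation). The division list had a median of -0.84 with 0 members called by limma (adjusted p = 0.0037; adjusted p = 0.5 with an estimated correlation; 0.052 without zone 1 replicate 1).

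In total 1957 probe sets changed between zones 1 and 4 by limma, 1427 higher (72.9%) and 530 lower in zone 4. With each array centred on its median, which moved the median log2 difference of all probe sets tested from 0.00 to -0.36, 2449 changed, of which 991 (40.5%) were higher and 1458 lower. The count was 678 without zone 4 replicate 1 and 426 without zone 4 replicate 2, and of the 46 called genes followed singly 28 and 18 kept the call. Without zone 1 replicate 1 or 2, 37 and 40 kept it, without either zone 2 array 42, and without either zone 3 array 45.

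The 2 sulfur deficiency marker genes tested did not pass the test for a difference between zones. SDI2 (AT1G04770), a gene induced by sulfur deficiency, had mean signals of 273 ± 31, 321 ± 190, 511 ± 300 and 249 ± 17 in zones 1 to 4 (SD, n = 2 each; F-test adjusted p = 0.44). The beta-glucosidase gene BGLU28 had 172 ± 190, 155 ± 140, 141 ± 120 and 108 ± 140 (adjusted p = 0.78). In the fixed list of sulfate assimilation, cysteine and glutathione genes, 3 members were tested. The ATP sulfurylase gene ATPS4 was 2.46-fold higher in zone 4 than in zone 1 (492 ± 210 against 195 ± 55, adjusted p = 0.044), the 1 member that passed in this comparison both over all genes tested and adjusted over the list alone. This call was lost when any array but zone 1 replicate 2 was left out (adjusted p from 0.054 to 0.34). ATPS3 and the sulfite reductase gene SIR had log2 differences of -0.66 and -0.45 there (adjusted p = 0.25 and 0.42). The list's camera test did not pass in any comparison (adjusted p = 0.35, 0.85, 0.35 and 0.86), and its median and mean had opposite signs between zones 4 and 1 (-0.45 and 0.06). A wider list of 20 sulfur, methionine and glucosinolate genes did not pass either (adjusted p = 0.58, 0.25, 0.59 and 0.29), though 2 of its members showed large differences. MGL, which encodes methionine gamma-lyase, was 11.2-fold higher in zone 2 than in zone 1 (548 ± 78 against 50.5 ± 18, adjusted p = 0.0057; 0.091 without zone 2 replicate 2). The glucosinolate transporter gene GTR1 was 8.49-fold higher in zone 4 than in zone 1 (958 ± 350 against 110 ± 25, adjusted p = 0.00073). The sulfate transporter genes had no named probe set here and were not analysed.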

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

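The 2 arrays left out together and the fixed lists alone were tests chosen after the results were seen. No direction reversed among 142 gene and 31 list results under any alternative run, and over all settings 381 gene calls and 95 list calls were lost and 29 gene calls gained. The causes of these changes were not tested. That no direction reversed was partly fixed in advance. Genes with the largest differences were named only where the 2 arrays of one zone lay above the 2 of the other. For them leaving out an array could not reverse the direction, and the 31 lists were followed because they had passed. Zone 4 against zone 3 was the count most open to the processing: from 288 it went to 93 with each array centred on its median, 37 without the trend, and 546 without zone 2 replicate 1 and zone 3 replicate 2. Zone 2 against zone 1 went from 1645 to 804 without the trend. Of 31 gene lists that passed, none did with an estimated correlation (0 by camera), fry called 13, of which 7 were among the 31, and the fixed lists alone gave 3. By comparison, fry kept 1 of 8 lists in zone 2 against zone 1 and 0 of 7 in zone 3 against zone 2. It kept 2 of 6 in zone 4 against zone 3 and 4 of 10 in zone 4 against zone 1. A lone array left in a zone was assumed to vary like the other zones. With 1 array left out at a time, 2196 to 3349 probe sets passed the F-test, zone 2 against zone 1 gave 70 to 1729, zone 3 against zone 2 gave 0 to 358, zone 4 against zone 3 gave 0 to 628, zone 4 against zone 1 gave 426 to 1956, and 24 to 33 lists passed. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered arrays correlated at -0.19 to 0.04, which shows no pairing but cannot exclude it. With a replicate block zone 4 against zone 3 gave 127. Apart from these, the counts stayed within 1.5 times the reported ones. Signals near the dim end of the arrays, as in zone 1 for many of the genes with the largest differences, limit how well folds are known.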

Other observations

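All 3 tests about the arrays of zones 2 and 3 were chosen after the result was seen. Single tubulin and defensin-like genes differed along the root, in lists that did not pass by camera. TUB1 had mean signals of 125 ± 34, 1540 ± 440, 3040 ± 1000 and 1520 ± 760 in zones 1 to 4 (SD, n = 2 each) and was 12.3-fold higher in zone 2 than in zone 1 (limma, adjusted p = 0.0018). TUB5 was 3.55-fold higher in zone 2 (adjusted p = 0.035). Over all genes tested these were the 2 higher genes among 7 tubulins, with none lower. Adjusted over the list alone, 3 were higher and 1 lower (list adjusted p = 0.28 by camera). The TUB5 call was lost without zone 1 replicate 1 (0.11), either zone 2 array (0.084 and 0.25) or either zone 4 array (0.059 and 0.058). The defensin-like genes LCR68 and LCR69 were higher in zone 4 than in zone 1 (3270 ± 1000 against 47.2 ± 7.8, and 594 ± 30 against 15.6 ± 17; log2 differences 6.09 and 5.97, adjusted p = 9.5e-05 and 0.0027). They were the 2 higher of 4 genes in their list, with 1 lower adjusted over the list alone. That list did not pass by camera (adjusted p = 0.2) and passed with fry (adjusted p = 0.042). With signals under the 40th percentile of their array raised to it, the log2 difference of LCR69 was 4.27.

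The dehydrin gene COR47 was 6.29-fold higher in zone 4 than in zone 1 (4330 ± 2600 against 736 ± 560, SD, n = 2, limma adjusted p = 0.025), and LTI30 was 5.48-fold higher in zone 2 than in zone 1 (adjusted p = 0.021). HVA22C, of the same list of 5 cold and dehydration genes, was lower in zone 2 than in zone 1 (log2 difference -1.60, SE 0.35, adjusted p = 0.019). The list had 1 higher and 1 lower member there and did not pass (camera, adjusted p = 0.43). In zone 4 against zone 1, with 3 higher members, it did not pass by camera (adjusted p = 0.099) and passed with fry (adjusted p = 0.019). COR47 was not called without zone 1 replicate 1 (0.11) or zone 4 replicate 2 (0.2), LTI30 without zone 1 replicate 2 (0.077), zone 2 replicate 1 (0.093) or zone 2 replicate 2 (0.11), and HVA22C without zone 2 replicate 2 (0.19). The glutathione transferase gene GSTU28 was 9.36-fold higher in zone 4 than in zone 1 (limma, adjusted p = 0.0039), and was not called without zone 4 replicate 2. Its list of 8, with 3 members higher, did not pass by camera (adjusted p = 0.088) and passed with fry (adjusted p = 0.019). Of 26 UDP-glucosyltransferase genes, 2 were higher and 1 lower in zone 2 than in zone 1, UGT71C4 at 4.69-fold higher (adjusted p = 0.16 without zone 2 replicate 2) and UGT76C2 lower by a log2 difference of -2.85, or -2.00 with dim signals raised to the 40th percentile of their array. That list passed with a median of 0.87 (adjusted p = 0.034; adjusted p = 0.5 with an estimated correlation) but not with quantile normalization (0.07), without zone 1 replicate 1 (0.28) or without zone 2 replicate 1 (0.12). It was also higher in zone 3 than in zone 2 (median 0.63, adjusted p = 0.00068; adjusted p = 0.44 with an estimated correlation) and lower in zone 4 than in zone 3 (median -0.50, adjusted p = 0.0017; adjusted p = 0.44 with an estimated correlation), with no member past the limma threshold. Neither held without zone 3 replicate 1 (0.063 and 0.12). In zone 4 against zone 1 the list had a median of 0.74 with 3 members higher (adjusted p = 0.028; adjusted p = 0.5 with an estimated correlation), which did not hold without zone 1 replicate 1 (0.3) or zone 4 replicate 2 (0.077).

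The first pattern weighed is the set of 252 probe sets higher in zone 4 than in zone 3, most of them highest in zone 1. The division list was higher in zone 4 by a median of 1.88 (limma's camera, adjusted p = 9.7e-07; adjusted p = 0.44 with an estimated correlation), which is in line with dividing cells in zone 4. Shoot tissue in the zone 4 sections cannot be told apart from root tissue that expresses such genes, because the nuclear photosynthesis list had a median of 0.70 with a camera p of 0.13 before adjustment. The 39 plastid-encoded genes had a median of 0.10, and the strongest zone 3 signals (up to 6590 for atpE) would hide a small share. Dimmer plastid-encoded genes went both ways, none of them called. From zone 3 to zone 4, psbA had mean signals of 399 and 292 and psbB 72.1 and 44.8, while psaC had 21.4 and 53 and psbH 16.7 and 54.1. Zone 1 tissue mixed into the zone 4 samples cannot be told apart from dividing cells of zone 4 itself. The 7 division genes called higher in zone 4 than in zone 3 put its share at 48% (38% to 84% from single genes). Because they were chosen as higher in zone 4, this share may be too high. Of 266 probe sets strong in zone 1, 35 (13.2%) lay under 0.5 times the level that share needs on both zone 4 arrays. This result lay between the bounds of 5% and 20% set for the test. Mixing at 1 uniform share would bring every such probe set to its needed level, so these 35 argue against 48%. A smaller share stays open. Single probe sets went both ways: against needed levels of 622 and 266, the zone 4 means were 132 for Hsp70-2 and 812 for AT4G27400. The difference between the zones as developmental stages stays open as well.

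The second pattern is that the 2 arrays of zone 2, and those of zone 3, lay apart along the direction from zone 1 to zone 3. A difference in where the sections were taken stays open, since the correlation chosen for it restates the pattern: over probe sets, the difference of the 2 zone 2 arrays correlated with zone 3 minus zone 1 at r = 0.42, and that of the zone 3 arrays with zone 2 minus zone 1 at 0.21. An exchange of the samples numbered 2 between zones 2 and 3 is argued against, since it would change the correlation of the 2 zone 2 arrays by -0.043 and of the 2 zone 3 arrays by -0.054. A difference in RNA quality cannot be told apart. In 3 of 3 control genes the array nearer to zone 1 had the higher 3'/5' ratio in one zone and the lower in the other. This was the outcome written down against RNA quality, but its size does not let it decide. In zones 2 and 3 the log2 differences in ratio were -0.80 and 0.81 for GAPDH, -0.48 and 0.43 for ubiquitin, and 1.27 and -1.17 for actin. Each was smaller than the largest between arrays of zones 1 and 4 (2.28, 0.75 and 1.5).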
